A study of Mus musculus with 18 samples.

How the data were processed

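Gene expression was measured with 1 Affymetrix whole-transcript array per sample in 9 small intestines and 9 livers, 18 arrays in all. Per the labels' protocols, total RNA was extracted with a column kit and biotin-labelled single-stranded cDNA was prepared from 250 ng of it. The deposited log2 values were made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes; versions are not given in the sources used here. RMA corrects background, normalizes quantiles across arrays and summarises probes into probe sets, and it narrows differences for dim probe sets. The log base is not stated and was taken as 2 from the range of the values, which carry 2 decimals; whether both tissues were normalized together is also not stated, so levels are compared within a tissue. No scan dates or batches were used here, so a batch that coincided with a donor group could not be told apart from it.

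The table holds 41345 probe sets. By the platform annotation used here, 23521 have 1 gene symbol, covering 22180 genes, 1814 have several and were not named, and 16010 are unnamed here. Symbols were looked up by gene identifier in a RefSeq table of assembly GRCm38.p6, which held 23328 of the 23521; the table served for names and gene classes only, and no coordinates are given because no build is named for the array. A probe set entered a tissue's test if it had 1 symbol and exceeded the array's median on at least 4 of the tissue's 9 arrays, and a gene was represented by its probe set of highest mean.

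Groups were taken from the sample titles, which call the samples biological replicates. No arrays held identical values. Within each tissue OMT was compared with YMT by limma (lmFit and eBayes, version 3.58.1, in R 4.3.3) on the deposited values, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists and cell type markers, 48 in all, were fixed before the data were examined; those with at least 5 tested members were tested by camera with a preset inter-gene correlation of 0.01, adjusted over the lists of that tissue. Whether the difference between OMT and YMT was unequal in the tissues was tested on all 18 arrays in 4 groups, with the probe set of highest mean over all arrays per gene, and the overlap of calls by Fisher's exact test. Figures were drawn with matplotlib.

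The genes named were chosen by a rule fixed before the data were examined: per tissue, the 10 largest rises and the 10 largest falls among genes past the threshold; from each list that shifted or held a gene past the threshold, up to 4 members of smallest p; Fgf21, Klb, Fgf15, Cyp7a1, Ppara, Sirt1, Mtor, Prkaa1, Prkaa2 and Igf1 whatever their p; and for the difference between tissues up to 5 genes per direction. Transcripts with only a clone, Gm or Rik name were passed over.

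The steps were tested on simulated arrays with added changes and the spread of the real ones. The simulated noise was independent between genes, unlike that of real arrays, so these shares may not hold for the real data. In intestine, with 13238 genes, 61.2%, 91.0% and 98.5% of the genes changed by 0.5, 1 and 2 on the log2 scale were recovered, and 6.3% of calls were genes that had not been changed. In liver, with 13380 genes, the shares were 73.1%, 100% and 100%, and 6.3%. For the difference between tissues, with 11965 genes, they were 32.8%, 92.5% and 98.5%, and 3.2%.

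Alternatives set before the data were examined were no filter or a stricter one at the 75th percentile, eBayes with trend and robust settings, all 18 arrays in the fit, array weights, quantile normalization or median centring within the tissue, the mean over a gene's probe sets, all probe sets, an estimated inter-gene correlation, the replicate number as a block, each array left out, and a threshold of 0.10. Added after the data were seen were the array's median or its snoRNA level as a covariate, the intestine without its 2 arrays of highest snoRNA level, and the liver without OMT replicates 1 and 2.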

Results

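The data are 18 mouse microarrays from young germ-free recipients, raised without any microbes, that were colonised with gut microbiota from either old or young donor mice. OMT recipients received microbiota from donors about 24 months old and YMT recipients from young donors. The labels give the young donors' age as 4 weeks in the protocol and as 5 to 6 weeks in the design text, and the recipients' age at sampling as 12 or 13 weeks. The animals carried the C57BL/6 background and were kept for 8 weeks after the transfer. Each tissue, small intestine and liver, contributed 5 OMT and 4 YMT arrays, 1 per biological replicate. The question the design addresses is how intestinal and hepatic metabolism differed with the age of the donor. The p-values rest on the spread among recipients. The number of donors or cages per group was not used here, so an effect of a shared donor or cage could not be told apart from donor age. Values below are log2 array levels as mean ± SD over 5 OMT and 4 YMT arrays, or differences of OMT minus YMT with the standard error (SE); adjusted p-values are from limma with Benjamini-Hochberg adjustment over the genes tested in that tissue. The number of arrays limits the precision.

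The tissue labels held on all 18 arrays. Hepatocyte markers averaged 11.41 to 11.49 on the liver arrays and 4.13 to 4.54 on the intestine arrays, and enterocyte markers 5.39 to 5.73 and 10.98 to 11.55. Albumin (Alb) lay between 13.21 and 13.26 in liver, and villin (Vil1), a protein of the intestinal brush border, between 11.97 and 12.27 in intestine. All arrays came from tissue with Y-linked transcripts: Eif2s3y lay between 7.17 and 8.23, while Xist, the transcript that silences an X chromosome in females, lay between 2.63 and 3.48. Array medians over all probe sets were 4.39 to 4.51 in intestine and 4.12 to 4.22 in liver.

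In the small intestine, 11 of 15 antigen presentation genes, 6 of 19 cholesterol synthesis genes and 4 of 14 goblet cell genes were lower in OMT than in YMT recipients, and 6 of 28 PPARalpha targets and 2 of 14 heat shock genes were higher. Each of these lists shifted by camera with a preset correlation, and each call was lost, at adjusted p = 0.764 with an estimated correlation. Of 13238 genes tested, 138 were higher and 410 lower in OMT at an adjusted p under 0.05, and 34 and 63 of these changed at least 2-fold. The counts were 274 and 367 after centring each array and 211 and 398 after quantile normalization within the tissue, so the share of higher calls depends on the scaling (25.2%, 42.7% and 34.6%). At an unadjusted p under 0.05 and a change of at least 1.5-fold, 609 genes stood out. The largest fall by point estimate was that of Gsdmc2 (probe set 17317442), a gasdermin of the gut epithelium, at 4.08 ± 1.30 in OMT and 7.47 ± 0.37 in YMT, a log2 difference of -3.40 ± 0.56 (adjusted p = 0.012). Its relative Gsdmc3 fell by 3.34 ± 0.48. The OMT means of Gsdmc2 (4.08) and Gsdmc3 (4.31) lay below the arrays' medians of 4.39 to 4.51, so the sizes of these falls are uncertain. The largest rise was that of Nt5e (probe set 17520073), an ectonucleotidase that makes adenosine, from 6.66 ± 0.82 to 9.36 ± 0.55, which is 6.48-fold (adjusted p = 0.00616).

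**Figure D1:**
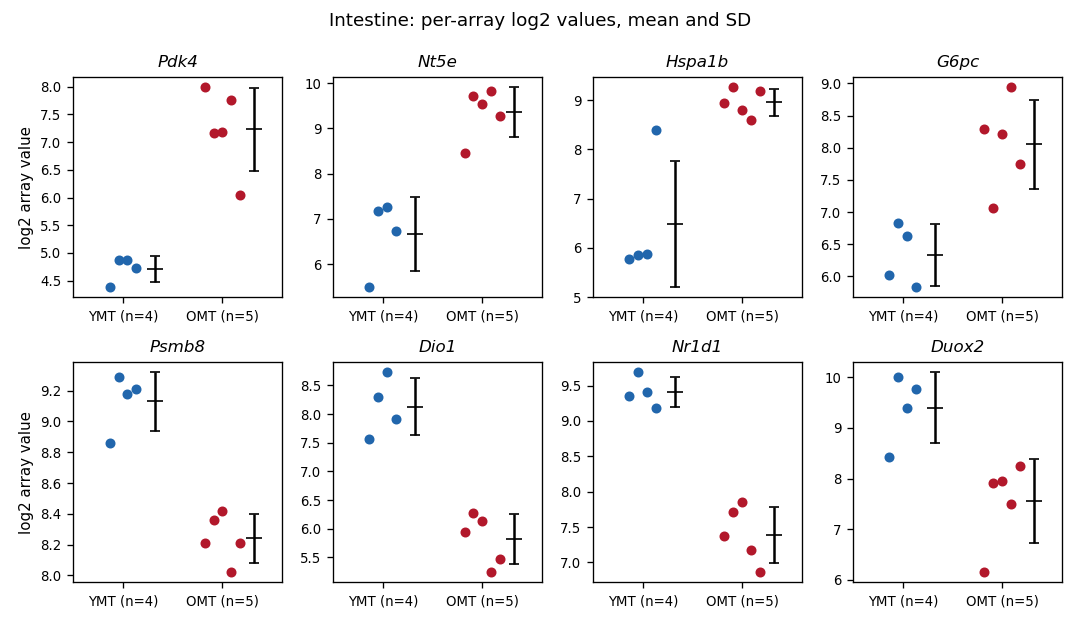
Log2 array values of 8 genes in the small intestine, with 1 point per array for 4 YMT and 5 OMT recipients and a bar for the mean ± SD beside each group. For Pdk4 and Nt5e every OMT array lies above every YMT array, and for Dio1, Nr1d1, Psmb8 and Duox2 every OMT array lies below.

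The other large intestinal rises were those of Pdk4, a kinase that restrains pyruvate oxidation (2.52 ± 0.33, adjusted p = 0.00548), Hspa1b (2.48 ± 0.48), Snora62 (1.92 ± 0.20), Angptl4, an inhibitor of lipoprotein lipase (1.89 ± 0.29). Next came Tm4sf4 (1.73 ± 0.28), Snora74a (1.73 ± 0.42), G6pc, the phosphatase that releases free glucose (1.72 ± 0.34), Ly6g6c (1.71 ± 0.34) and Ces1g (1.70 ± 0.36). Falls of similar size were found for Dio1, a deiodinase of thyroid hormone (-2.31 ± 0.27), the interferon-induced ligase Herc6 (-2.23 ± 0.40), the adhesion adaptor Tns4 (-2.08 ± 0.22) and the protease inhibitor Csta2 (-2.04 ± 0.15, adjusted p = 0.000419), whose OMT mean of 3.85 also lay below the arrays' medians. They were followed by the clock repressor Nr1d1 (-2.01 ± 0.19), the iron exporter Slc40a1 (-2.01 ± 0.46), the desaturase Scd1 (-2.00 ± 0.39) and ccdc198 (-1.93 ± 0.27). In naming these, 2 transcripts with only a clone-like name were passed over. Of the rises, Snora62 and Snora74a are snoRNAs. The 64 snoRNA genes tested in intestine had a median change of 0.41, against -0.03 for protein-coding genes, so these 2 rises are not apart from their class.

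Of 15 measured antigen presentation genes, 11 fell in the OMT intestine and none rose (13 when adjusted over the list alone), with a median change of -0.66. The immunoproteasome subunits Psmb10 (10.11 ± 0.10 in YMT and 9.14 ± 0.19 in OMT, adjusted p = 0.00303) and Psmb8 (-0.89 ± 0.11) fell, as did the class II genes H2-Ab1 (-0.79 ± 0.10) and H2-DMa (-0.88 ± 0.13). Of 25 interferon response genes 5 fell (19 when adjusted over the list alone; median -0.77), among them Irgm1 (-0.94 ± 0.17), Zbp1 (-1.90 ± 0.41), Bst2 (-1.13 ± 0.27) and the transcription factor Irf7 (-0.86 ± 0.20). Of the markers of T cells and NK cells, Gzmb (-1.43 ± 0.27) and Gzma (-0.96 ± 0.22), granzymes of cytotoxic cells, fell (4 when adjusted over the list alone), and the other 16 of 18 did not pass, Cd3e being at -0.61 ± 0.16 (adjusted p = 0.0619). Goblet cell genes fell in 4 of 14 (9 when adjusted over the list alone), namely Klk1 (-1.66 ± 0.23), Clca1 (-0.82 ± 0.16), Tpsg1 (-0.79 ± 0.16) and Bcas1 (-0.49 ± 0.11). Of 15 antimicrobial and microbe-induced genes, Duox2, a source of hydrogen peroxide (9.40 ± 0.70 to 7.55 ± 0.83, adjusted p = 0.0426), and Lypd8 (-0.94 ± 0.21) fell (2 when adjusted over the list alone), while Reg3g was at -0.99 ± 0.39 (adjusted p = 0.169). Cell cycle genes fell in 2 of 29 (15 when adjusted over the list alone), namely Ccnb2 (-1.10 ± 0.22) and Cdc20 (-0.90 ± 0.19).

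Among metabolic lists, cholesterol synthesis fell in 6 of 19 members (17 when adjusted over the list alone; median -0.67), with Nsdhl (-1.46 ± 0.20), Cyp51 (-1.26 ± 0.22), Tm7sf2 and Ebp (-0.60 ± 0.10) named by the smallest p. Of 28 PPARalpha targets, genes of fatty acid oxidation and ketogenesis, 6 rose and 1 fell (12 and 2 when adjusted over the list alone; median 0.37), including Acaa2 (1.19 ± 0.19) and Pex11a (0.95 ± 0.15) beside Pdk4 and Angptl4. Ppara itself was at 0.42 ± 0.13 (adjusted p = 0.0879). Lipid absorption held 1 rise, that of Apoc2 (1.68 ± 0.35), and 1 fall, that of the sterol exporter Abcg5 (-0.56 ± 0.11), among 23 members with a median of 0.21 (8 and 2 when adjusted over the list alone). Fatty acid synthesis went both ways, with Elovl6 (-1.29 ± 0.23), Scd1 and Acss2 (-0.84 ± 0.17) among 4 falls and Dgat2 (0.72 ± 0.14) the 1 rise of 19 (8 and 2 when adjusted over the list alone). Oxidative phosphorylation fell in 2 of 37 (10 when adjusted over the list alone), Sdha (-0.37 ± 0.08) and Ndufa9 (-0.38 ± 0.09). Of 14 heat shock genes Hspa1b and Hspa8 (0.60 ± 0.11) rose, 12 when adjusted over the list alone, with a median of 0.51. Hspa1b was at 8.40 on YMT replicate 4 and between 5.78 and 5.87 on the other YMT arrays. Of 15 clock genes Cry2 (0.66 ± 0.08) and Cry1 (0.81 ± 0.15) rose and Nr1d1 and Dbp (-0.68 ± 0.16) fell (4 and 2 when adjusted over the list alone). The bile acid receptor Nr1h4 fell by 0.92 ± 0.18 and its target Nr0b2 rose by 0.58 ± 0.12. Fgf15, the intestinal hormone that restrains bile acid synthesis, was at 9.42 ± 1.18 in OMT and 9.69 ± 0.50 in YMT (adjusted p = 0.789). Sirt1 (-0.18 ± 0.07), Mtor (-0.15 ± 0.08), Prkaa1 (-0.46 ± 0.13), Prkaa2 (-0.83 ± 0.31) and Igf1 (0.06 ± 0.08) did not pass, and Fgf21, Klb and Cyp7a1 did not reach the level filter.

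By camera, 11 of 39 lists shifted in the intestine at an adjusted p under 0.05: antigen presentation (1.39e-11), cholesterol synthesis (3.03e-10), interferon response (3.79e-07), cell cycle (1.99e-06), goblet cells (4.07e-06), T cells and NK cells (0.00146), oxidative phosphorylation (0.00349) and antimicrobial genes (0.0448) downward. Heat shock proteins (1.64e-09), PPARalpha targets (6.32e-05) and lipid absorption (0.000762) shifted upward. For all 11 the call is lost at adjusted p = 0.764 with an estimated correlation, and 41 of 100 splits of the arrays gave at least 11 list calls. The snoRNA level was 7.23 ± 0.52 in OMT and 6.74 ± 0.20 in YMT intestines (exact permutation p = 0.151, two-sided), highest on OMT replicates 1 and 2 (7.92 and 7.58). Without these arrays, an alternative chosen after the data were seen, 78 genes were higher and 156 lower. Without YMT replicate 2 the counts were 37 and 113, and they moved by more than 1.5-fold without OMT replicates 2 (63 and 164) or 3 (50 and 226) or YMT replicates 1 (77 and 209) or 4 (68 and 170).

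In the liver, 18 of 21 fatty acid synthesis genes and 10 of 17 male-biased genes were lower in OMT than in YMT recipients. Higher were 11 of 13 heat shock genes, 12 of 21 unfolded protein and ATF4 response genes and 11 of 23 acute phase genes. So were 7 of the 9 female-biased genes measured, out of 18 listed. The level filter can admit a gene by its OMT arrays alone and leaves out a gene that is low in both groups. The share of rises among female-biased genes may therefore be too high. With an estimated correlation the list of unfolded protein and ATF4 responses kept its call (adjusted p = 0.0378). The calls of the other lists were lost, at adjusted p = 0.0903 for fatty acid synthesis, 0.116 for male-biased genes, 0.0774 for heat shock and for female-biased genes and 0.164 for acute phase genes. Of 13380 genes tested, 1388 were higher and 1175 lower, 129 and 142 of them by at least 2-fold, and 969 genes passed an unadjusted p under 0.05 with a change of at least 1.5-fold. The counts fell to 740 and 719 with the replicate number as a block, and quantile normalization within the tissue gave 1156 and 1492, so which direction holds more genes depends on the scaling. Scd1 (probe set 17365098), the desaturase that makes monounsaturated fatty acids, fell from 12.72 ± 0.17 to 7.35 ± 1.82, or 41.4-fold (adjusted p = 0.000768), with a wide spread among OMT livers. Slco1a1 (probe set 17472385), a male-biased transporter of organic anions, fell from 9.63 ± 0.10 to 5.07 ± 0.30, or 23.6-fold (adjusted p = 4.89e-08). Fmo2 (probe set 17229036), a flavin monooxygenase, rose 14-fold from 6.09 ± 0.31 to 9.90 ± 0.26 (adjusted p = 5.9e-07).

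**Figure D2:**
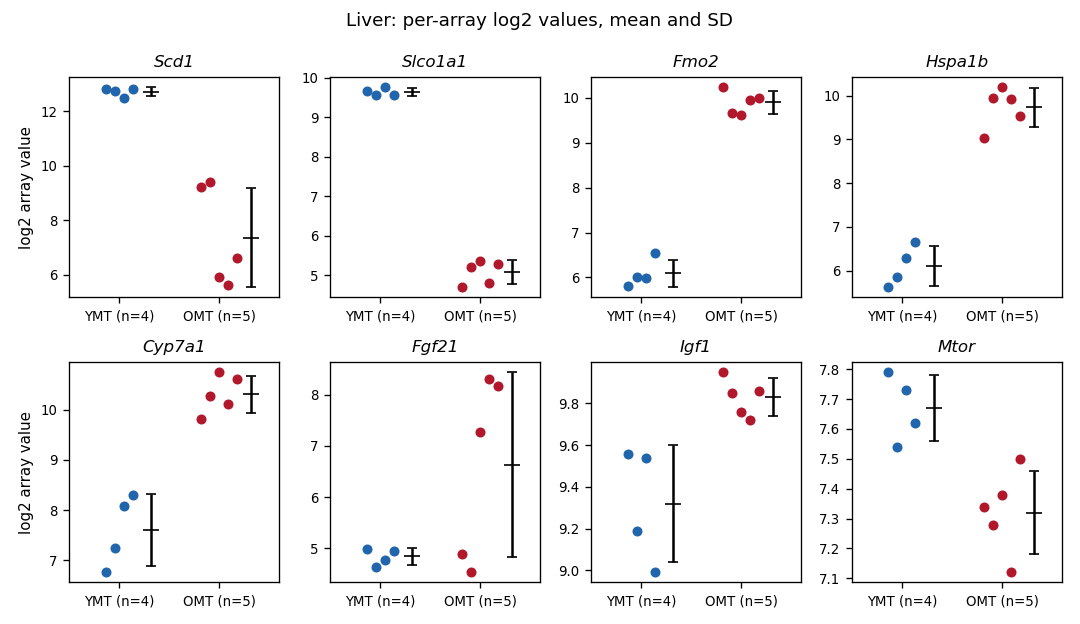
Log2 array values of 8 genes in the liver, with 1 point per array for 4 YMT and 5 OMT recipients and a bar for the mean ± SD beside each group. OMT and YMT arrays do not overlap for Scd1, Slco1a1, Fmo2, Hspa1b, Cyp7a1, Igf1 and Mtor; for Fgf21 OMT replicates 1 and 2 lie at 4.88 and 4.53, near the YMT mean of 4.84, and the other OMT arrays between 7.28 and 8.31.

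The other large rises in liver were those of Hspa1b (3.62 ± 0.25), the transporter Slc16a5 (3.21 ± 0.23), Acnat2 (2.93 ± 0.18), the endoplasmic reticulum protein Creld2 (2.83 ± 0.22), Cyp7a1, the rate-limiting enzyme of bile acid synthesis (2.71 ± 0.30, adjusted p = 0.000218). Smaller rises were those of Acot3 (2.65 ± 0.26), Socs2, a feedback inhibitor of growth hormone signalling (2.52 ± 0.39), Lcn2 (2.49 ± 0.30) and Hsph1 (2.42 ± 0.19). The other large falls were those of Hsd3b5 (-4.02 ± 0.32), Hamp2 (-3.97 ± 0.30), the elongase Elovl3 (-3.34 ± 0.33), G6pc (-3.24 ± 0.29), Mup-ps12 (-3.13 ± 0.36, with an OMT mean of 3.14, below the arrays' medians), Rgs16 (-3.04 ± 0.35), the water channel Aqp8 (-3.00 ± 0.29) and Thrsp (-2.88 ± 0.21). For these, 1 transcript with only a clone-like name was passed over. Probe sets of close relatives, such as the Mup, Cyp3a, Acot, Gsdmc and Hspa1 genes, can detect each other's transcripts.

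Of 21 measured fatty acid synthesis genes 18 fell and none rose in the OMT liver (21 fell when adjusted over the list alone), with a median of -1.78. Besides Scd1 and Thrsp, the falls included Acacb (-2.74 ± 0.25), Fasn, the fatty acid synthase (11.84 ± 0.38 in YMT and 9.12 ± 0.52 in OMT, adjusted p = 7.45e-05), and Pklr (-2.23 ± 0.15). Cholesterol synthesis fell in 6 of 19 (6 fell and 1 rose when adjusted over the list alone), among them Tm7sf2 (-1.14 ± 0.11), Sc5d (-1.13 ± 0.13), Dhcr7 (-0.96 ± 0.22) and Nsdhl (-1.26 ± 0.33). PPARalpha targets went both ways, with 7 rises, such as Acot4 (1.72 ± 0.12) and Cyp4a14 (1.59 ± 0.19), and 6 falls, such as Acaa1b (-1.61 ± 0.09) and Fabp1 (-1.35 ± 0.09), of 31 (9 and 6 when adjusted over the list alone). Of 17 male-biased liver genes 10 fell (12 when adjusted over the list alone; median -0.76), led by Slco1a1, Hsd3b5, Elovl3 and Nudt7 (-1.78 ± 0.18). Of 9 female-biased genes 7 rose and 1 fell (the same counts when adjusted over the list alone; median 1.59), with Fmo2, Trim24 (2.06 ± 0.11) and Acot3 among the rises and Cyp3a44 (-1.42 ± 0.18) the fall. These 9 genes passed a level filter that can favour genes that rose, which may raise the share and the median.

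Of 13 heat shock genes 11 rose in the OMT liver (12 when adjusted over the list alone; median 0.97), including Hsp90aa1 (1.29 ± 0.09) and Hspa8 (0.90 ± 0.09). Of 21 unfolded protein and ATF4 response genes 12 rose (15 when adjusted over the list alone; median 0.82), with Sdf2l1 (2.39 ± 0.17), Manf (1.19 ± 0.12) and Herpud1 (1.07 ± 0.11) beside Creld2. Of 23 acute phase genes 11 rose and 12 did not pass (11 rose and 1 fell when adjusted over the list alone; median 0.23), with Apcs (1.85 ± 0.13), Lbp (1.29 ± 0.13), Itih3 (1.11 ± 0.10) and Hp (0.73 ± 0.06) named by the smallest p. Interferon response genes fell in 15 of 25 and rose in 1 (17 and 1 when adjusted over the list alone; median -0.55), with Bst2 (-1.58 ± 0.18), Irf7 (-1.21 ± 0.14), Iigp1 (-0.72 ± 0.10) and Oasl2 (-0.72 ± 0.10) among the falls. Antigen presentation fell in 9 of 14 (10 when adjusted over the list alone; median -0.60), with Psmb8 at -0.92 ± 0.10. Endothelial markers fell in 7 of 14 (9 when adjusted over the list alone), such as Cdh5 (-0.75 ± 0.10). Of the others, stellate cell and fibroblast markers fell in 8 of 15 and rose in 1 (9 and 1 when adjusted over the list alone), such as Col14a1 (-1.61 ± 0.20) and Col3a1 (-0.94 ± 0.15). Macrophage markers fell in 4 of 17 (6 when adjusted over the list alone), such as Clec4f (-0.68 ± 0.09), while Marco rose by 1.66 ± 0.19. Oxidative phosphorylation fell in 9 of 37 (10 when adjusted over the list alone), with Ndufb3 at -0.64 ± 0.11. Without OMT replicates 1 and 2, an alternative chosen after the data were seen, this list's median went from -0.17 to -0.07 and its call was lost (adjusted p = 0.141).

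Among signalling genes fixed beforehand, Fgf21, a hormone of the fasted liver, was at 1.80 ± 0.74 and did not pass (adjusted p = 0.119), and its co-receptor Klb (0.11 ± 0.14) did not pass either. Its values split the OMT livers, with 4.88 and 4.53 on replicates 1 and 2 and 7.28 to 8.31 on the others. The same 2 livers stood apart for Scd1 (9.21 and 9.40 against 5.63 to 6.61), Cyp1a2 (10.67 and 10.87 against 8.87 to 9.23) and Cidec (5.97 and 5.83 against 7.48 to 7.79). Without them, an alternative chosen after the data were seen, 1156 genes were higher and 985 lower. Igf1 rose by 0.51 ± 0.12 (adjusted p = 0.0129) and its carrier Igfals by 0.90 ± 0.14. Mtor fell by 0.35 ± 0.09 (adjusted p = 0.02) and the AMPK subunit Prkaa2 by 0.56 ± 0.11. The autophagy kinase Ulk1, named like Igfals for its small p within a list, fell by 1.72 ± 0.11. Of 24 genes of AMPK, SIRT1 and mTOR signalling 1 rose and 4 fell (median -0.06). Of 14 genes of the growth hormone and IGF1 axis 4 rose and 2 fell (median -0.02). Neither list shifted by camera (adjusted p = 0.222 and 0.626). Without the same 2 livers Igf1 at 0.46 (adjusted p = 0.0591) and Mtor at -0.34 (adjusted p = 0.0682) did not pass but kept about the same size, while Fgf21 passed at 3.08 (adjusted p = 6.78e-05), where the livers left out are those with its low values. Sirt1 (-0.07 ± 0.08), Ppara (-0.15 ± 0.09), Prkaa1 (-0.14 ± 0.10) and Fgf15 (0.04 ± 0.11) did not pass. Of 15 clock genes 6 rose and 5 fell (7 and 5 when adjusted over the list alone), with Cry1 at 1.06 ± 0.12, Cry2 at 0.53 ± 0.10, Nr1d1 at -1.62 ± 0.35 and Bhlhe41 at -1.03 ± 0.19. The nuclear receptor Nr1i3 rose by 1.92 ± 0.17, and of its neighbours in the xenobiotic list Cyp3a13 rose by 1.28 ± 0.13 and Cyp2c55 fell by 1.89 ± 0.23. A further probe set of Cyp2c55, the one used for the difference between tissues, gave -3.30 in liver.

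By camera, 12 of 31 lists shifted in the liver: fatty acid synthesis (adjusted p = 5.79e-17), male-biased genes (2.44e-08), interferon response (9.77e-08), antigen presentation (8.04e-06), endothelial cells (1.62e-05), oxidative phosphorylation (0.000296), stellate cells and fibroblasts (0.00171) and macrophages (0.00234) downward. Heat shock proteins (1.77e-11), unfolded protein and ATF4 responses (1.20e-08), female-biased genes (8.04e-06) and acute phase genes (0.000127) shifted upward. The call for unfolded protein and ATF4 responses held at adjusted p = 0.0378 with an estimated correlation. The others were lost, at adjusted p = 0.0774 for heat shock proteins and female-biased genes, 0.0903 for fatty acid synthesis, 0.116 for male-biased genes, endothelial cells and stellate cells, 0.131 for interferon response and antigen presentation, 0.164 for acute phase genes, 0.407 for macrophages and 0.716 for oxidative phosphorylation, each with an estimated correlation. Of 100 splits of the liver arrays 8 gave at least 12 list calls, and normalizing quantiles within the tissue again moved the share of higher calls from 54.2% to 43.7%.

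**Figure D3:**
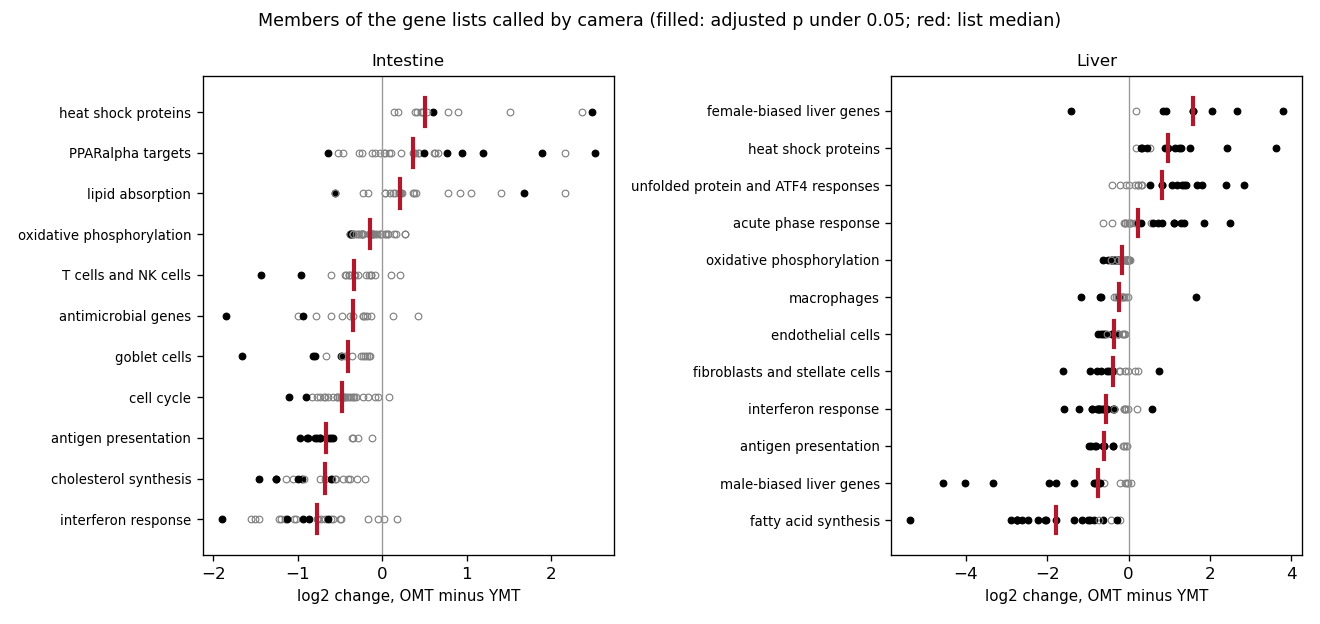
Log2 change, OMT minus YMT, of each measured member of the lists that shifted by camera, 11 in intestine and 12 in liver, with filled points for members past an adjusted p of 0.05 and a red bar for the list's median. Medians reach -0.77 for interferon response in intestine and -1.78 for fatty acid synthesis in liver, and 1.59 for the 9 female-biased genes in liver that passed the level filter.

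The difference between OMT and YMT was unequal in the tissues for 1429 of 11965 genes tested in both, 946 with a more positive change in liver and 483 with a more negative one. G6pc rose in intestine (1.72) and fell in liver (-3.24), a difference of -4.97 ± 0.48 (adjusted p = 3.56e-06). Fmo2 (3.70 ± 0.23), Slc16a5 (3.21 ± 0.26), Trim24 (2.08 ± 0.18), Impact (1.85 ± 0.17) and Eif1a (1.51 ± 0.14) changed more positively in liver, and Acacb (-3.11 ± 0.29), Ttc39c (-2.23 ± 0.19), Ces2e (-1.82 ± 0.15) and Gamt (-1.42 ± 0.12) more negatively. As a list, fatty acid synthesis differed by a median of -1.21 (adjusted p = 3.87e-14, and adjusted p = 0.0843 with an estimated correlation), stellate cell and fibroblast markers by -0.29 (adjusted p = 0.0454, and adjusted p = 0.857 with an estimated correlation) and unfolded protein and ATF4 responses by 0.66 (adjusted p = 2.66e-07, and adjusted p = 0.0256 with an estimated correlation). This test of lists between tissues was chosen after the data were seen. Without intestine YMT replicate 4, 949 genes differed.

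Calls were shared between the tissues more often in the same direction than independent lists would give. Of 11970 genes tested in both, 45 rose in both where independent lists expect 13 (Fisher's exact test, one-sided p = 1.14e-14), and 96 fell in both where 29.6 are expected (p = 1.71e-26); genes are not independent, so these p-values are too small. Genes that rose in intestine and fell in liver numbered 8 against 10.3 expected, and the converse 17 against 37.3. Among the shared genes, Hspa1b, Creld2, Cry1 and Cidec rose in both tissues and Dio1 (-2.31 and -2.59), Scd1, Nr1d1 and Nsdhl fell in both. The log2 changes correlated across genes at Pearson r = 0.22 and Spearman rho = 0.16.

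**Figure D4:**
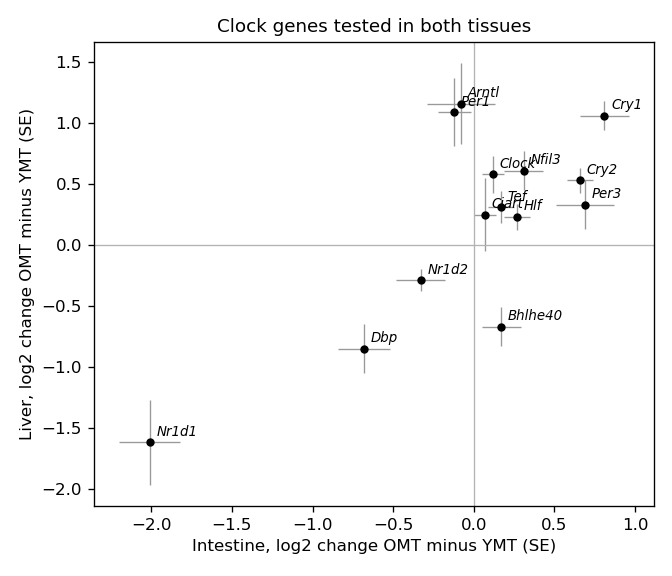
Log2 change, OMT minus YMT, of 14 clock genes tested in both tissues, intestine on the horizontal and liver on the vertical axis, with lines for the SE. Nr1d1 (-2.01 and -1.62) has the lowest value on both axes, Cry1 (0.81) the highest in intestine and Arntl (1.16) the highest in liver, and 11 of the 14 genes have the same sign in both tissues.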

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

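Tests of a time of day, a fasted state, the share of hepatocytes, the sex of the mice and growth hormone, and the test of lists between tissues, were chosen only after the results they concern had been seen. Of 486 groups of values of named genes, 24 held a sample far from the others, and chance gives about 1 in 20 groups. OMT replicate 1 of intestine stood apart for Cd3e at 7.12 (others 7.73 to 7.82) and Sh2d7 at 5.71 (others 5.07 to 5.23). OMT replicate 4 of intestine stood apart for Ces1g at 7.96 (others 5.93 to 6.46) and Insr at 7.40 (others 7.10 to 7.15). OMT replicate 5 of intestine stood apart for Pparg at 5.72 (others 5.85 to 5.87) and Igf1 at 4.78 (others 4.48 to 4.54). YMT replicate 1 of intestine stood apart for Cyp51 at 9.20 (others 8.60 to 8.65), Zbp1 at 7.70 (others 9.24 to 9.40) and Nkg7 at 6.62 (others 7.05 to 7.08). YMT replicate 2 of intestine stood apart for Birc5 at 4.83 (others 5.19 to 5.26). YMT replicate 3 of intestine stood apart for Angptl4 at 5.75 (others 6.44 to 6.56). YMT replicate 4 of intestine stood apart for Hspa1b at 8.40 (others 5.78 to 5.87), Snora74a at 5.37 (others 6.38 to 6.44), Hspa1a at 8.05 (others 4.60 to 5.16) and Hsph1 at 8.60 (others 6.49 to 6.57). OMT replicate 1 of liver stood apart for Tap2 at 4.49 (others 4.94 to 5.09). OMT replicate 3 of liver stood apart for Cyp3a44 at 3.56 (others 4.36 to 4.60). OMT replicate 4 of liver stood apart for Rrm2 at 4.89 (others 4.31 to 4.44) and Sdha at 10.61 (others 10.69 to 10.72). YMT replicate 1 of liver stood apart for Nr1d1 at 9.76 (others 8.62 to 8.81) and Pck1 at 10.78 (others 11.44 to 11.56). YMT replicate 2 of liver stood apart for Mpeg1 at 8.80 (others 7.84 to 7.94). YMT replicate 3 of liver stood apart for Cyp1a2 at 11.68 (others 11.56 to 11.58). YMT replicate 4 of liver stood apart for Tapbp at 8.00 (others 8.20 to 8.24).

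The difference between OMT and YMT was unequal in liver and intestine by limma's interaction term, at an adjusted p under 0.05, for 67 of 150 named genes tested. Many of these were named for large changes or small p-values in these same data, which can raise the share. Over all genes tested in both tissues it was 1429 of 11965 (11.9%). For 28 of them the change was more positive in liver, the log2 differences being Fmo2 3.70, Slc16a5 3.21, Socs2 2.93, Slc40a1 2.57, Trim24 2.08, Sdf2l1 2.02, Creld2 1.92, Lcn2 1.89 and Zbp1 1.88. Further values were Lbp 1.82, Marco 1.63, Herc6 1.52, Treh 1.35, Nr1h4 1.27, Cyp3a13 0.98, Acot4 0.96, Herpud1 0.90 and Hp 0.88. The smallest were H2-DMa 0.84, Irgm1 0.81, Hsp90aa1 0.76, Prodh 0.73, Hyou1 0.70, Manf 0.63, Cps1 0.62, Ebp 0.52, Bsg 0.37 and Insr 0.35. For 39 it was more negative in liver, led by G6pc -4.97, Fabp1 -3.52, Scd1 -3.37, Angptl4 -3.24, Acacb -3.11, Pdk4 -2.70, Cyp3a11 -2.41, Fasn -2.26, Acaa1b -2.22 and Pklr -2.11. Next came Nt5e -1.90, Nudt7 -1.90, Pck1 -1.84, Cyp2c55 -1.83, Apoc2 -1.68, Ly6g6c -1.66, Snora74a -1.66, Ces1g -1.65, Ulk1 -1.36 and Elovl6 -1.33. Smaller ones were Acaa2 -1.32, Fosb -1.31, Acss2 -1.21, Col14a1 -1.20, Cyp27a1 -1.20, Dusp1 -1.16, Dgat2 -1, Tiparp -0.96, Tm4sf4 -0.93 and Reln -0.87. The remainder were Gulo -0.85, Sc5d -0.83, Cyp2f2 -0.80, Ndufb3 -0.78, Enpep -0.60, Gip -0.57, Ppara -0.57, Ltc4s -0.56 and Clec4f -0.52. The value of Cyp2c55 rests on a probe set with a liver change of -3.30, against -1.89 for the one used within the liver. Among lists the median difference was -1.21 for fatty acid synthesis, 0.66 for unfolded protein and ATF4 responses and -0.29 for stellate cell and fibroblast markers. With an estimated correlation the call for unfolded protein and ATF4 responses held (adjusted p = 0.0256), and those for fatty acid synthesis (adjusted p = 0.0843) and for stellate cells and fibroblasts (adjusted p = 0.857) were lost.

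By camera the clock list shifted in neither tissue (adjusted p = 0.0519 in intestine and 0.37 in liver). Camera tests a shift in 1 direction and can miss a list whose members both rise and fall, as these did. Of 15 clock genes measured in each tissue 4 passed in intestine and 11 in liver, Nr1d1, Cry1, Cry2 and Dbp in both. A different time of day at sampling may account for this: the log2 changes of 14 clock genes in intestine and liver correlated across genes at Pearson r = 0.74 (permutation p = 0.00399, two-sided) and Spearman rho = 0.42 (permutation p = 0.138), and genes are not independent replicates. The relation rests on Nr1d1, without which r was 0.47 (permutation p = 0.105), and in the liver Nr1d1 was high on YMT replicate 1. An effect of the donors' microbiota on the clock in both tissues would give the same values, and no sampling times were used here, so the explanations remain open.

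Of 21 fatty acid synthesis genes 18 fell in the OMT liver, with a list median of -1.78, and the list's call was lost at adjusted p = 0.0903 with an estimated correlation. A fall in the share of hepatocytes as large as that of these genes is argued against by the hepatocyte markers. Their median change was -0.04 with an SD of 0.26 among members. A smaller change of share was not tested and might not show, since Alb (13.21 to 13.26) lay near the liver arrays' maxima (13.24 to 13.36). A fasted state may lower these genes, but 22 measured fasting-induced genes were at 7.99 ± 0.33 in OMT and 8.27 ± 0.09 in YMT livers, a difference of -0.28 (exact permutation p = 0.175, two-sided), with 4 higher and 8 lower. The bound that would exclude fasting was narrowed after a first outcome had been seen, under which the value had counted against it; by the bound used here fasting cannot be told apart from the donor group. The age of the donor stays open as an untested biological explanation.

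In the OMT liver 10 of 17 male-biased genes fell. Of 9 female-biased genes measured among 18 listed, 7 rose and 1 fell. The level filter can favour genes that rose, so this share may be too high. By camera both lists lost their call (adjusted p = 0.116 and adjusted p = 0.0774 with an estimated correlation). Female mice among the OMT livers are argued against by Xist, at most 3.21 in OMT and 3.48 in YMT livers, and by Eif2s3y, at least 7.67 in OMT livers. Continuous in place of pulsed growth hormone signalling may shift both lists. Bcl6 (-2.39 ± 0.40), Cux2 (0.85 ± 0.16) and Socs2 (2.52 ± 0.39) passed, but Cish was at 0.03 ± 0.27 (adjusted p = 0.956), which decides neither way. Cux2 is itself on the female-biased list and Socs2 had been named for the size of its rise, so neither is separate evidence. A first version of this test counted all 4 genes and had come out in favour of the explanation; it was replaced by Cish alone after that outcome had been seen. The age of the donor stays open as an untested biological explanation.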

How the results depend on the processing

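The covariates of array median and snoRNA level and the fits without the 2 intestine arrays of highest snoRNA level and without OMT livers 1 and 2 were chosen only after the results had been seen. No named gene or list changed its direction while past the threshold under any alternative run. Leaving out 1 array at a time, 47 of 71 named genes past the threshold in intestine and 14 of 107 in liver lost their call at least once, as did 1 of 11 lists in intestine and 0 of 12 in liver. Arrays resolve dim probe sets poorly, and the simulated arrays give the changes that could be recovered if genes varied independently of each other.

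The intestine counts of 138 higher and 410 lower genes became 382 and 949 at an adjusted p of 0.10, 78 and 232 with no filter, 365 and 1081 with all 18 arrays in the fit, 368 and 804 with array weights, and 72 and 217 over all probe sets. They became 74 and 115 with the array median as a covariate, 85 and 124 with the snoRNA level as a covariate, and 78 and 156 without the 2 arrays of highest snoRNA level. Of the 138 higher and 410 lower genes, 31 and 98 were also called with the array median, 52 and 121 with the snoRNA level and 52 and 152 without the 2 arrays. Of 71 named genes past the threshold, 42, 38 and 39 lost their call under these alternatives, and of 11 lists 3, 1 and 1 did. The higher count became 211 after quantile normalization and 274 after centring, where the lower counts were 398 and 367. The share of higher calls was 25.2% as reported, 34.6% after quantile normalization and 42.7% after centring; in liver it was 54.2%, 43.7% and 49.3%. The count at an unadjusted p and 1.5-fold became 963 in intestine and 1628 in liver over all probe sets, where more features were tested. With an estimated correlation 0 lists shifted in intestine and 1 in liver. Genes that differed between tissues numbered 2274 at an adjusted p of 0.10, and genes shared in the same direction 385 at that threshold and 78 with no filter, against 141. A looser threshold and a larger number of tests change counts by construction; otherwise the cause was not tested.

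With 1 array left out, intestine counts ranged from 37 to 155 higher and 113 to 481 lower, both lowest without YMT replicate 2; they also moved by over 1.5-fold without OMT replicates 2 (63 and 164) and 3 (50 and 226) and YMT replicates 1 (77 and 209) and 4 (68 and 170). Liver counts ranged from 928 to 1514 higher and 872 to 1166 lower, and the difference between tissues from 949, without intestine YMT replicate 4, to 1670. Without OMT livers 1 and 2, 1156 genes were higher and 985 lower in liver, and 12 of 107 named genes and 1 of 12 lists, oxidative phosphorylation (median -0.17 to -0.07, adjusted p = 0.141), lost their call. Most of the 12 genes kept about the same size on fewer arrays, such as Dusp1 (-0.92 to -0.93), Atf3 (0.38 in both), Jun (0.73 to 0.69) and Sdha (-0.20 to -0.22). Cox6b1 (-0.42 to -0.26), Cox5a (-0.43 to -0.32) and Glul (-0.34 to -0.26) moved more.

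With the replicate number as a block, 740 genes were higher and 719 lower in liver and 111 and 347 in intestine. The numbers do not show a pairing. For this, each gene's mean over its donor group was subtracted, and the remaining deviations were correlated across genes. Between arrays of the same number in both donor groups these deviations correlated at -0.06 to 0.32 in intestine and -0.18 to 0.09 in liver. Between intestine and liver arrays of the same number they correlated at -0.04 to 0.08 in OMT and 0.01 to 0.15 in YMT. Both tissues of a group may still come from the same mice, which is not known here. With donor group and number as a block over both tissues, 1550 genes differed between tissues, against 1429.

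Of 100 splits of the intestine arrays, only the real one reached 138 higher (highest other 0) and 410 lower genes (highest other 1). The same held for 609 at an unadjusted p (highest other 393). In liver only the real split reached 1388 higher (153), 1175 lower (85) and 969 at an unadjusted p (627). A random grouping of the arrays is thus an unlikely source of these counts, each with 1 split as large. For the difference between tissues 2 of 100 splits, the real one included, reached 1429. The other gave 1524, above the real count, so chance is unlikely there but not excluded. Splits cannot tell the donor group apart from a batch or sampling time that coincided with it. Chance cannot be excluded for the number of lists: 41 splits gave at least 11 in intestine (highest other 18) and 8 at least 12 in liver (highest other 15).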

Other observations

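The genes in this part were grouped by hand only after their values had been seen, and no explanation was tested for them, so no shared change of a group is claimed. Of these genes Hamp2, Slc40a1, Dio1 and Thrsp had been named for the size of their change. Fixed lists hold Thrsp and Me1 (fatty acid synthesis), Hamp (acute phase response) and Slc40a1, Slc11a2 and Cybrd1 (proximal small intestine). Among genes of iron handling, in liver the hepcidin gene Hamp was at 0.02 ± 0.18 (adjusted p = 0.963), while its paralogue Hamp2 fell (-3.97 ± 0.30). The transferrin receptor Tfrc rose in liver by 2.02 ± 0.14 and the transporter Slc11a2 by 0.73 ± 0.13. The exporter Slc40a1 fell in intestine (-2.01 ± 0.46) and rose by 0.56 ± 0.10 in liver. The heme exporter Flvcr1 rose by 1.05 ± 0.17 in intestine and 0.70 ± 0.14 in liver, and Slc46a1 fell in both (-0.78 ± 0.16 and -0.60 ± 0.08). Tfrc was at 0.54 ± 0.17 (adjusted p = 0.0951) and Slc11a2 at -0.13 ± 0.10 (adjusted p = 0.448) in intestine. In intestine and liver Cybrd1 was at -0.02 and 0.09 (adjusted p = 0.942 and 0.546) and Fth1 at -0.22 and 0.15 (adjusted p = 0.145 and 0.167).

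Some genes of nuclear RNA and RNA binding passed in both tissues and others in neither. Neat1, a long noncoding RNA of nuclear paraspeckles, rose by 0.65 ± 0.13 in intestine and 1.80 ± 0.42 in liver, Tardbp by 0.40 ± 0.08 and 1.06 ± 0.11, Ddx17 by 0.35 ± 0.07 and 1.19 ± 0.13, and Nktr by 0.43 ± 0.10 and 0.84 ± 0.25. In intestine and liver Clk1 was at 0.37 and 0.39 (adjusted p = 0.139 and 0.155), Clk4 at 0.17 and 0.44 (adjusted p = 0.491 and 0.0835) and Cirbp at -0.51 and -0.31 (adjusted p = 0.0599 and 0.153). Of genes that thyroid hormone induces in liver, Gpd2 (-1.61 ± 0.09) and Me1 (-2.47 ± 0.28) fell beside Dio1 and Thrsp. Klf9 was at 0.10 ± 0.14 in liver (adjusted p = 0.685) and fell in intestine (-0.47 ± 0.11). Fkbp5, which glucocorticoids induce, rose by 1.71 ± 0.14 in liver and was at 0.85 ± 0.22 in intestine (adjusted p = 0.0566), and Tsc22d3 rose by 0.73 ± 0.10 in intestine and was at 0.22 ± 0.16 in liver (adjusted p = 0.376).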
